A study of Mus musculus with 2 samples.

How the data were processed

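The series holds 2 libraries from primary mouse embryonic fibroblasts, 1 made by chromatin immunoprecipitation (ChIP) with an antibody against Brg1 and 1 from input chromatin without an antibody. Chromatin was released with micrococcal nuclease and brief sonication, and libraries were prepared after Helicos guidelines, per the labels' protocols. The submitters' processing notes name Bowtie and the genome build mm9, with no version and no settings. The values are counts: each deposited file lists a chromosome, a strand, a position and the count of tags at that position, and no normalization is recorded. What filter on repeated tags the authors used is not given in the sources used here. In the files, the ChIP has at most 2 tags at a position, with 110702 of 13470565 listed positions at 2 (0.822%, Clopper-Pearson 95% interval 0.817 to 0.827). The input has at most 1 tag at a position on 18 autosomes, and up to 2 on chromosomes 9, X and Y. Plus-strand tags made up 49.9% of each library. The files do not say whether positions count from 0 or from 1, so positions are printed as the files give them and may be off by 1 bp; the last listed position on chromosome 1 was 197195398.

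Tags were counted in windows of 1000 bp after each was moved 75 bp along its strand. ChIP counts were scaled to the input by the autosomal totals, 2.36 ChIP tags per input tag. Windows with at least 10 tags in the sum of both libraries, 26.7% of 2641888, were tested with a two-sided exact binomial test on the tags of the 2 libraries, with Benjamini-Hochberg adjustment. A window was called at an adjusted p under 0.05 and a ratio of at least 1.5, or of at most its inverse, and adjacent called windows were merged. Ratios have exact conditional (Clopper-Pearson) 95% intervals. Where a library had 0 tags, a floor of 3 tags per region took its place; this bound leaves out the counting error of the other library, so the exact 95% bound is given beside it. The regions named were the 12 merged enriched regions with the highest lower 95% bound and the 5 in the other direction with the lowest upper bound. This rule, the tests above and most alternatives were fixed before the data were examined. The adjusted p of a merged region is the lowest of its windows.

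Distances between tags were counted on the autosomes up to 1000 bp. Maxima were read from a 31 bp running mean after a quadratic trend over 120 to 800 bp was removed, and the repeat is the slope of a line through the first 3. Each of these was sought in its own preset range of distances, so 3 maxima are found in any curve. Errors are jackknife SEs over the 19 autosomes. For the profile around enriched windows, the tags of each library were split at random into 2 equal parts. Autosomal windows with an unadjusted p under 0.001 and a ratio of at least 1.5 in the first part were measured in the second. This profile was devised after the data were seen, in place of one around transcription starts.

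The planned results on promoters, gene bodies and fixed gene lists need an annotation on mm9 coordinates. The gene table at hand is on another assembly, GRCm38, and coordinates were not converted, so these results are not analysed here.

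The steps were tested on simulated data. Counts for the real windows were drawn from Poisson distributions with the mean and depth of these libraries, and 200 windows each were raised 2-fold, 4-fold and 8-fold. The window test, run on 754547 simulated windows, called 0% of the 2-fold, 6.50% of the 4-fold and 84.0% of the 8-fold windows, and 3 unchanged windows. Unchanged windows had a shared mean in both libraries and no spread beyond Poisson, so their calls do not measure false calls in the real libraries. A simulated repeat of 190 bp was recovered as 190 bp. Its maxima lay inside the preset ranges, so a repeat outside them was not tried. For the profile, the ChIP tags were divided at random into a mock ChIP and a mock input. The 540 windows selected on its first part at p under 0.05, the looser value being needed to have windows to measure, had a held-out ratio of 1.04 (0.981 to 1.10).

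The alternatives tried for the windows were other scalings, removal of repeated tags, no movement of tags, other minimums, window sizes and ratios, and a local floor on the input. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.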

Results

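Brg1 is the ATPase subunit of Swi/Snf, a complex that moves and evicts nucleosomes. Its binding was profiled in primary embryonic fibroblasts taken from wild-type mouse embryos of mixed C57BL/6 and 129 background at E13.5. Nuclear chromatin was cut with micrococcal nuclease, which digests the linker DNA between nucleosomes, and was then briefly sonicated. Fragments precipitated with an antibody against Brg1 made up 1 library, and chromatin taken without an antibody, the input, made up the other. The ChIP library held 13581267 tags, of which 13215004 lay on autosomes. The input held 5778620 tags, of which 5608004 lay on autosomes. On average a 1 kb window of an autosome held 5.47 ChIP tags and 2.32 input tags. With 1 library per group there was no replicate check, so the tests below compare the tags of these 2 libraries and not conditions, and all intervals cover counting error only.

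Both libraries had a first maximum of tag pairs at a nucleosome-sized distance. Pairs were counted from a tag to the next tags on the same strand, and maxima were sought within preset ranges after removal of the trend. In the ChIP library they lay at 174, 367 and 533 bp, which gave a repeat of 179.5 ± 8.95 bp (jackknife SE over 19 autosomes). In the input the maxima lay at 171, 377 and 579 bp, with a repeat of 204 ± 44.2 bp. The difference between these repeats was smaller than the error of the input value. Because the ranges were preset, the repeats alone do not show that the later maxima stand out. At the first maximum the ChIP library held 1.09 times the pairs found at 900 to 1000 bp and the input 1.03 times, against 1.05 and 1.00 in the troughs that followed. At short range both libraries showed a step close to 10 bp, which is about the length of a turn of the DNA helix. It measured 10.1 ± 0.102 bp in the ChIP library and 10.2 ± 0.0986 bp in the input, with amplitudes of 1.80% ± 0.0651 and 2.30% ± 0.150. From plus-strand to minus-strand positions the most frequent distance was 36 bp in the ChIP library and 37 bp in the input. Whether the position of a minus-strand tag is its start or its leftmost base is not given in the sources used here, so this distance is not read as a fragment length.

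**Figure D1:**
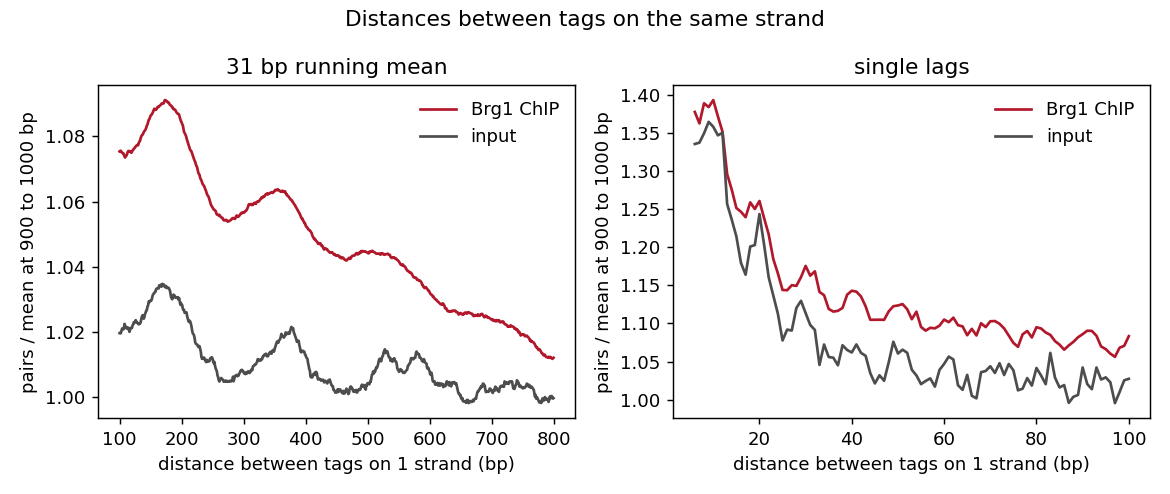
Pairs of tags on the same strand by the distance between them in bp, relative to the mean at 900 to 1000 bp, for the Brg1 ChIP (red) and the input (grey). The left panel, a 31 bp running mean, shows the first broad maximum at 174 bp in the ChIP and 171 bp in the input; the right panel, at single distances, shows the steps of about 10.1 and 10.2 bp.

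To ask where in the genome Brg1 was enriched, ChIP and input tags were compared in 1 kb windows. Of 706215 windows with enough tags to test, 2684 held more ChIP tags than the input predicted, and 47 held fewer (exact binomial test, two-sided, Benjamini-Hochberg adjusted). The enriched windows formed 2501 regions, of which 2335 were a single window wide, 150 spanned 2 windows, 15 spanned 3 and 1 spanned 4. They held 110172 ChIP tags, or 0.811% of the library, and 3981 input tags, or 0.0689%. The median enriched window had 40 ChIP tags and 1 input tag, and 609 of them had no input tag. Without adjustment, 42209 windows were higher and 12008 lower at the same threshold of p. The number of enriched windows depended strongly on the settings. It ranged from 9 with 500 bp windows to 15946 with a minimum of 20 tags, and was 35 when the input of a window was not allowed to fall below its mean over 10 kb.

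Among the 12 regions with the highest lower bound of enrichment, the first lay on chromosome X at 103382000 to 103382999, with 135 ChIP tags against 2 input tags, a ratio of 28.6 after scaling (95% interval 7.78 to 239, exact test, adjusted p = 2.21e-12). By their listed positions, 125 ChIP tags there fell within 477 bp, a narrower block than in the enriched autosomal windows, which is taken up among the further observations. On chromosome 4, the region at 128866000 to 128867999 held 68 ChIP tags and 0 input tags, so that it was at least 9.62-fold higher against a floor of 3 tags, with an exact lower 95% bound of 7.61 (exact test, adjusted p = 0.00455). A second region on that chromosome, at 45502000 to 45503999, had 99 ChIP tags against 1 (ratio 42.0, interval 7.37 to 1676, exact test, adjusted p = 0.000152). On chromosome 3, the 3 windows from 97828000 to 97830999 held 98 against 1 (ratio 41.6, interval 7.29 to 1659, exact test, adjusted p = 0.0181). Regions with a single input tag were also found on chromosome 11 at 74643000 to 74644999, where 87 ChIP tags gave a ratio of 36.9 (6.45 to 1475), and on chromosome 13 at 63666000 to 63667999, where 86 gave 36.5 (6.38 to 1458).

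In the remaining 6 regions the input had no tag. They lay on chromosome 12 at 109416000 to 109417999 (65 ChIP tags, at least 9.19-fold higher, exact lower bound 7.27), on chromosome 8 at 73062000 to 73063999 (63 tags, at least 8.91-fold, exact bound 7.04), on chromosome 18 at 55150000 to 55151999 (61 tags, at least 8.63-fold, exact bound 6.81), on chromosome 10 at 21510000 to 21510999 (60 tags, at least 8.49-fold, exact bound 6.69), on chromosome 2 at 4803000 to 4803999 (59 tags, at least 8.35-fold, exact bound 6.58) and on chromosome 16 at 77014000 to 77014999 (57 tags, at least 8.06-fold, exact bound 6.35). Their adjusted p ranged from 0.000143 on chromosome 10 to 0.0130 on chromosome 18. Because regions were ranked on their own counts, these ratios carry the bias of that selection. With the input held at or above its mean over 10 kb, the regions on chromosome X and chromosome 10 were still called and the other 10 were not. Under that setting the 4 regions printed with ratios of 36.5 to 42.0 fell to between 4.61 and 6.08, and the lowest of the 12 was 3.34, on chromosome 8. The region on chromosome 16 lost its call with its value unchanged at 8.06. The region on chromosome 4 at 128866000 lost its call at 7.21, against 9.62 in the main setting. Coordinates are those of mm9; an annotation of that build was not used here, so the genes at these regions are not given.

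**Figure D2:**
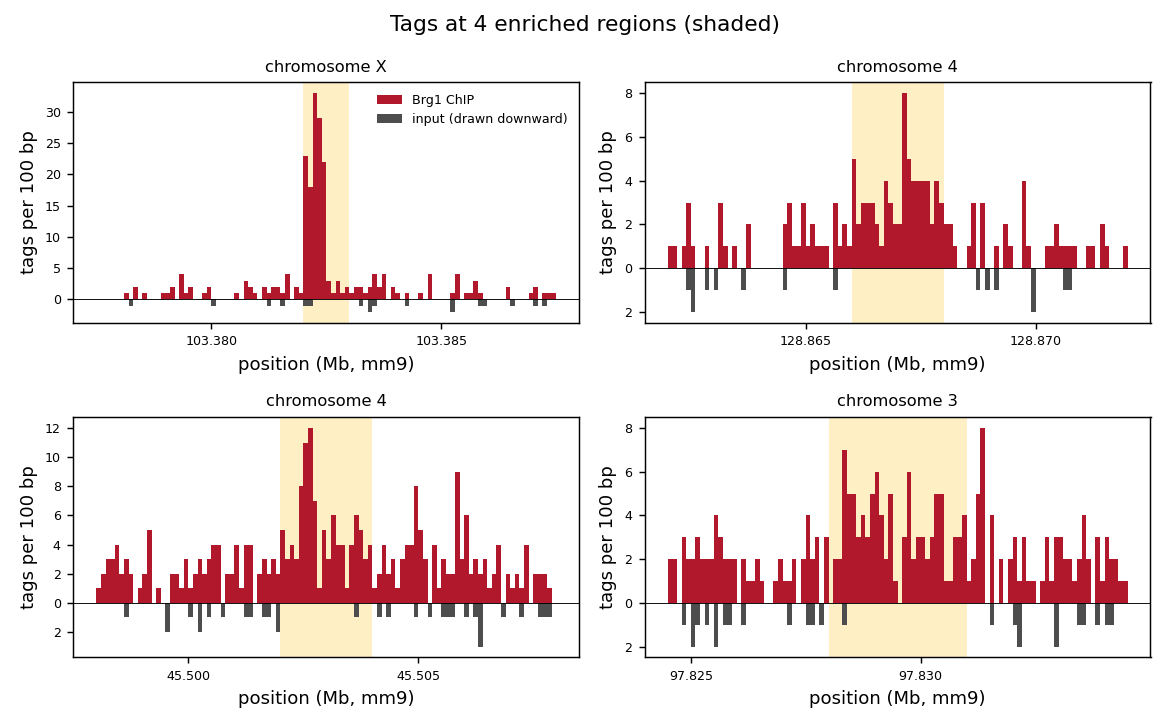
Tags per 100 bp over 10 kb around the 4 regions with the highest lower bound of enrichment (shaded), by position in Mb of mm9, after each tag was moved 75 bp along its strand; ChIP tags are drawn upward in red and input tags downward in grey, on a scale that differs between panels. On chromosome X the tags stand in a narrow block, and in the panels for chromosomes 4 and 3 they spread over the shaded region and beyond it.

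In the other direction, 45 regions held fewer ChIP tags than the input predicted. Of the 5 named by the same rule, the strongest was on chromosome 4 at 139558000 to 139558999, with 0 ChIP tags against 12 input tags, a ratio of at most 0.106 against the floor of 3 tags, with an exact upper bound of 0.153 (exact test, adjusted p = 0.00388). On chromosome 5 at 130817000 to 130817999 and on chromosome 7 at 82217000 to 82217999 the counts were 0 against 10, with a ratio of at most 0.127, an exact upper bound of 0.189 and an adjusted p of 0.0129 for each. The regions on chromosome 14 at 67555000 to 67555999 and on chromosome 5 at 112992000 to 112992999 held 1 against 11, a ratio of 0.0386 (0.000896 to 0.265, exact test, adjusted p = 0.0198). None of these 5 calls held with a minimum of 20 tags, since none of the windows has that many.

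To reduce the effect of this selection, windows were chosen on a random 1 of 2 equal parts of the tags of each library and measured on the other part. In the 528 autosomal windows chosen in this way, held-out ChIP tags were at 7.24 times the autosomal mean in the central 1 kb (95% interval 7.10 to 7.38) and input tags at 1.53 times (1.43 to 1.63), a ChIP/input ratio of 4.74 (4.43 to 5.07). At 1.5 to 2.5 kb from the centre the ratio was 2.18 (2.07 to 2.30), and at 4 to 5 kb it was 1.53 (1.45 to 1.61). At 9 to 11 kb it was 1.31 (1.26 to 1.36), and at 90 to 100 kb it was still 1.17 (1.15 to 1.19). Input tags did not dip below their surroundings at these windows: they were at 1.53 times the mean in the centre and 1.39 times (1.32 to 1.46) at 4 to 5 kb. Since the choice of windows used the input of the first part, the same number of windows was also ranked by ChIP tags. Windows with 10 or more input tags in the first part were left out of this ranking, so the input still entered it. In the windows ranked by ChIP tags the held-out input was at 1.79 times the mean in the centre (1.68 to 1.90). It was at 1.42 times (1.35 to 1.49) at 4 to 5 kb, and the central ratio was 4.59 (4.31 to 4.88). The ratio with the left-out windows included was not measured. At 528 windows drawn at random the central ratio was 0.974 (0.887 to 1.07). The adjusted threshold left 2 windows on the first part, so the windows were taken at an unadjusted p under 0.001, at which 10 autosomal windows were lower.

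**Figure D3:**
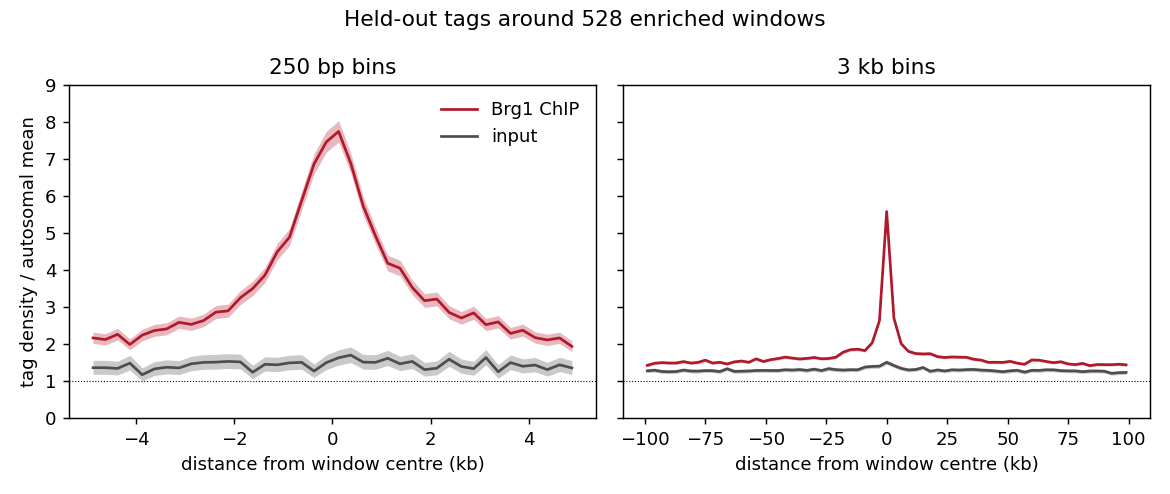
Held-out tag density relative to the autosomal mean, by distance in kb from the centre of 528 windows chosen on the other part of the tags, for the Brg1 ChIP (red) and the input (grey), with 95% counting intervals shaded; the dotted line is the mean. The ChIP peaks in the centre, where the central 1 kb is at 7.24 times the mean, and both libraries remain above 1 as far as 100 kb from the centre.

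Enrichment also differed between chromosomes. Relative to the autosomes together, the ChIP/input ratio was highest on chromosome 19 at 1.04 (1.03 to 1.04) and chromosome 11 at 1.04 (1.03 to 1.04), and lowest among autosomes on chromosome 14 at 0.972 (0.967 to 0.976). Chromosome X was lower than every autosome at 0.914 (0.909 to 0.919). Chromosome Y was lower again at 0.710 (0.676 to 0.746), from 4180 ChIP tags and 2498 input tags. Enriched windows followed the autosomal order at both ends, with 18.3 per 10000 windows on chromosome 19 and 7.61 on chromosome 14. Per 1000 tested windows the values were 5.20 and 3.18. ChIP tag density was 1.13 times that of the autosomes on chromosome 19 and 0.885 times on chromosome 14, so density may enter this order. Chromosome X had 5 enriched windows, or 0.306 per 10000 (0.0992 to 0.713), against 11.1 on the autosomes. Tag density on chromosome X was 0.404 times that of the autosomes in the ChIP and 0.443 times in the input, so that fewer of its windows could pass. The input lists up to 2 tags per position on chromosomes 9, X and Y and at most 1 on the other 18 autosomes, and this difference enters the values of chromosomes X and Y. Chromosome 9, with the same listing, was at 0.984 (0.980 to 0.989), within the range of the autosomes. With at most 1 tag per position chromosome X was at 0.920 and chromosome Y at 0.713, so both stayed low without the second tags.

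**Figure D4:**
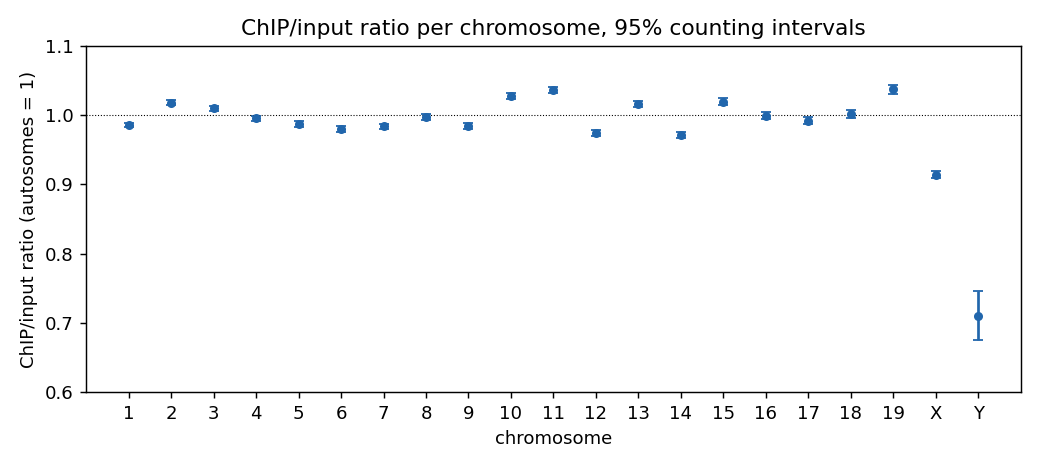
ChIP/input ratio of each chromosome relative to all autosomes (dotted line at 1), with 95% counting intervals as bars; the vertical axis starts at 0.6. The autosomes lie between 0.972 and 1.04, chromosome X at 0.914 and chromosome Y at 0.710.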

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

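The windows of 10 kb, the removal of tags within 5 bp, the omission of chromosomes 9, X and Y, the scaling of chromosome ratios to all chromosomes and every alternative for the held-out profile were chosen after the data were seen. The count of enriched windows, 2684 higher and 47 lower, moved most. It was 6353 higher with background scaling, which lowered the scale to 0.898 of its value. A minimum of 20 tags gave 15946 higher and 78 lower from 82067 tested windows, no minimum 715 and 7 from 2421806, so that fewer and more tests, in turn, entered the adjustment. Windows of 500 bp gave 9 and 1, windows of 2 kb 7418 and 328, and windows of 10 kb 9952 and 2786. With the input held at or above its mean over 10 kb there were 35 and 9, a setting that by construction removes calls resting on a low input count. With 1 tag per strand within 5 bp there were 369 and 5; the cause was not tested. Scaling to all chromosomes, 1 tag per position, unmoved tags, a ratio of at least 2 and omission of chromosomes 9, X and Y kept both counts within 1.5 times. Of 155 values for the 12 higher regions 130 kept the call, 25 lost it and 0 changed direction. Of 65 for the 5 lower regions 41 kept it and 24 lost it. A kept call did not always mean a kept ratio. With 10 kb windows all 12 higher regions kept their calls, but their ratios fell to between 1.91 and 4.40. The calls lost with 500 bp windows were lost at unchanged ratios, since the ratio was there summed over all 500 bp windows of a region. It is therefore no measure of enrichment at that width. The held-out ratio of 4.74 was 4.03 in 4130 windows selected at p under 0.01 and 5.29 in 92 selected at p under 0.0001, as a stricter selection takes stronger windows, and stayed inside its interval under another split, 1 tag per position and unmoved tags. It was not measured with 1 tag per strand within 5 bp, and a random split can put such neighbouring tags in both parts. The ratio of chromosome X was 0.920 with 1 tag per position, just outside its interval. That setting took 818 of 168118 input tags from chromosome X and none from 18 autosomes, which raises this ratio. The repeats and the 10 bp step moved by less than their errors with 1 tag per position. The alternatives set for promoters, promoter profiles, gene compartments and gene lists were not run, since no annotation of mm9 was used. No paired analysis was possible because each group has 1 library. At 2.32 input tags per window, depth limits the calls: a window with 0 input tags needed at least 27 ChIP tags.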

Other observations

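The 10 kb windows and their thinning, the covariance, the excess variance, the split of dense windows by chromosome, the tests on the pile-up and the values of the input per chromosome were chosen after the results they bear on were seen, and the thinning of autosomes at 1 kb and the test of positions shared in dense windows were set before their own results were. Over 10 kb windows, 9952 of 249877 tested (3.98%) held more ChIP tags than the input predicted and 2786 held fewer. The higher windows merged into 7969 regions, of which 44 spanned at least 5 windows. Both of the widest were 80 kb. The region on chromosome 14 at 120670000 to 120749999 held 1584 ChIP and 267 input tags, a ratio of 2.52 (2.21 to 2.88), and that on chromosome 11 at 117800000 to 117879999 held 1699 and 316, a ratio of 2.28 (2.02 to 2.58). The region with the highest lower bound was a single 10 kb window on chromosome 6 at 146830000 to 146839999, with 246 ChIP tags against 16, a ratio of 6.52 (3.94 to 11.6). It was followed by another on chromosome 6 at 49160000 to 49169999, with 258 against 18, a ratio of 6.08 (3.77 to 10.4). On chromosome X, the window at 11700000 to 11709999 had 136 against 8, a ratio of 7.21 (3.56 to 17.0). The share of tested 10 kb windows that were higher was 5.77% on chromosome 11, 5.44% on chromosome 19 and 3.07% on chromosome 14, the lowest autosome. It was 0.996% on chromosome X (144 of 14451) and 0% on chromosome Y (0 of 203).

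The difference between ChIP and input density was shared by windows far apart. Its covariance between autosomal 1 kb windows was 0.261 ± 0.0201 (SD over 19 autosomes) for adjacent windows, 0.0711 ± 0.00664 at 10 kb, 0.0302 ± 0.00716 at 100 kb and 0.00765 ± 0.00559 at 500 kb.

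Chromosome X had few enriched windows. When autosomal tags were thinned to its density in 20 draws, 0.185 ± 0.0294 windows per 10000 (SD over draws) passed the same threshold of p, inside the interval of chromosome X scaled in the same way to its own totals, 0.428 (0.172 to 0.881) from 7 windows. Lower tag density could therefore account for the few calls at 1 kb. At 10 kb it remains open whether density is enough: 1.35% of the tested windows of chromosome X were higher when it was scaled to its own totals (1.17 to 1.55), against 1.65% of thinned autosomal windows (1.60 to 1.68 over draws), and single thinned autosomes ranged from 1.44% on chromosome 14 to 1.99%, all above the value of chromosome X but not all above its interval. Whether local enrichment is weaker there cannot be told apart from no difference either, since the excess variance of ChIP tags less their covariance with the input was 0.326 on chromosome X and 0.347 on chromosome 11, the lowest autosome on this measure, a difference of -0.0213 with an SE of 0.0574; without that subtraction chromosome X stood at 0.736 and the lowest autosome, chromosome 9, at 0.520. No biological explanation was tested, since the design has a single cell type.

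The pile-up on chromosome X was narrower than the enriched autosomal windows. From 103382062 to 103382538, 125 ChIP tags at 121 distinct positions and strands, 48 on the plus and 77 on the minus strand, stood at 118 times the chromosome's mean (98.6 to 141). Extra copies of the segment in the cells would raise the input as much, and its 2 tags put it at 4.08 times the mean with an upper bound of 14.7. Its core-to-flank ratio was 13.8, against a median of 1.93 and a highest value of 7.53 in the 2679 enriched autosomal windows, and 0 of these reached it, but this restates the narrowness by which the pile-up was noticed and does not bear on its origin. A DNA fragment from outside the chromatin in the ChIP library stays open for the core; it would leave the flanking kilobases near the mean, and they held 8.59 times the mean (6.08 to 11.8), at or above the flanks of 2642 of those windows, so that the flanks need another source, and Brg1 binding at the locus stays open too.

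Windows dense in input tags had a low ratio. Windows were grouped by the tags in a random 1 of 2 equal parts of the input and measured with the other part: the ratio rose from 0.942 (0.940 to 0.945) with 0 tags to 1.15 (1.14 to 1.16) with 5 to 9, and was 0.760 (0.730 to 0.792) in the 166 autosomal windows with 10 or more. Chromosome 11 held 82 of these windows, 75 of them below position 3200000, at a ratio of 0.730 (0.693 to 0.769). Chromosome 9, where the input also lists up to 2 tags per position, held 20, at 0.454 (0.397 to 0.520). Of those 20, 15 lay below that position. The 64 on the other autosomes were at 0.964 (0.890 to 1.04), which is also below the 1.15 of windows with 5 to 9 tags. A limit on tags per position could flatten the ChIP in the dense windows if both lists were nearly full. In these windows 13.6% (12.4 to 14.9) of the held-out input positions were also listed by the ChIP, against 3.42% for evenly spread positions. That is between the values set in advance for and against the limit, so its part cannot be told apart, and no biological explanation was tested.

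The input listed repeated tags differently between chromosomes, and the reason was not tested. It listed 1162 positions with 2 tags on chromosome 9, 818 on chromosome X and 31 on chromosome Y, and 0 of 5304556 on the other 18 autosomes. Pairs of input tags 1 bp apart on the same strand were at 0.604 times the mean at 6 to 30 bp on those 18 autosomes (range 0.554 to 0.679) and at 2.17 times on chromosomes 9, X and Y (range 1.87 to 3.04). In the ChIP library the 18 autosomes were at 1.72 (range 1.66 to 1.76) and chromosome 9 was also at 1.72, while chromosome X was at 2.41 and chromosome Y at 3.45.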
